A study of Homo sapiens with 8 samples.

How the data were processed

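Total RNA from 8 samples of the HSC-2 line was extracted with Trizol, per the labels' protocols, and each sample was labelled with Cy3 and hybridised to 1 single-colour Agilent array with 60901 non-control spots of 58201 probes. The authors' deposited scanner files give spot intensity values made with Feature Extraction 11.5.1.1, per the file headers, and the processed signal in them is already corrected for background. The headers name the human build hg19 for the array's design. The authors' deposited series matrix holds log2 values, and a comparison with the scanner values showed what they are: the log2 processed signal minus the 75th percentile over its 33800 rows, which are the features well above background on at least 1 array. Scale, centring and direction are thus settled. The medians of its columns were -2.65, -2.66, -2.66 and -2.68 for the normal samples and -2.37, -2.40, -2.41 and -2.42 for the adhesion-restricted samples. Groups and replicate numbers came from the sample titles.

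Probes were named through their RefSeq accessions, without versions, in a table of RefSeq genes of GRCh38.p14, used for names only. Of the 58201 probes, 31104 matched 1 symbol, giving 22439 symbols, 27097 matched none and 0 matched several. Unnamed probes were kept under the accession or name in the files. The log2 processed signal was computed for each spot, the array's 75th percentile over non-control spots was subtracted, 2075 control spots and spots flagged as non-uniform or population outliers were left out, and spots of a probe were averaged. Probes well above background on at least 4 of the 8 arrays were kept (26597), and each gene was represented by its probe with the highest mean over all 8 arrays, which left 21685 genes. The probes of 440 among 3981 genes with several probes disagreed in direction.

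The comparison of 4 adhesion-restricted with 4 normal samples used lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment, a threshold of 0.05 and, for the stricter counts, a 2-fold change. All p-values are two-sided. The 42 gene lists were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were measured, and adjusted over the 40 tested lists. Genes were named by a rule fixed at the same time as the comparison: the 8 largest increases and 8 largest decreases past the threshold, without overlap of the groups, with a probe well above background in all 4 samples of at least 1 group and with a gene symbol; 24 genes chosen beforehand; and for each list up to 4 members past the threshold with the largest changes. Some genes that the rule or the counts would name are not reported here. Other names are marked as chosen after their values were seen. A gene not well above background on any array of 1 group has only a bound, the mean of the brighter group against, per array, the higher of the lowest signal well above background and the gene's own. The median SD within a group was 0.069 in normal and 0.082 in adhesion-restricted samples. The arrays' number limits the precision.

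Other settings fixed before the data were examined were quantile normalization, median scaling, no scaling, normexp background correction with an offset of 50 followed by quantile normalization, the series matrix values, 2 other filters on dim probes, 2 other ways to treat several probes of a gene, flagged spots kept, saturated probes left out, a trended and robust variance model, array weights, the replicate number as a block, each sample left out in turn, camera with an estimated correlation, and fry. Because the deposited files hold no mean signal, normexp was run on the median signal and the median local background. Scaling on the 7 spike-in controls that were well above background throughout, and a set test among protein-coding genes only, were added after the data were seen.

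The tests were also run on simulated arrays with the real genes' means and spreads, where 200 of 21680 genes were changed by known factors for this comparison. limma recovered 42% of the genes changed 1.2-fold, 74% at 1.5-fold, 80% at 2-fold and 100% at 4-fold, and 4.52% of 155 calls were false. The set test called the 1 shifted list and 0 of the others. Noise was drawn for each gene independently, so the simulation cannot show how the set test behaves with correlated genes. It also changed few genes, whereas 79.1% were called in the real data, so its recovery and false shares need not hold there. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Slide and scan were the same for all arrays and could not be tested as batches.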

Results

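Transcript levels were measured across the genome in HSC-2, an established human oral squamous cell carcinoma cell line, under 2 culture conditions. The normal condition was represented by 4 samples kept in medium with 10% fetal bovine serum. For the adhesion-restricted condition, 4 samples came from cells grown for 72 hours in 24-well NanoCulture plates, also with 10% serum. The finely patterned surface of these plates limits cell attachment. The series' own design text gives this culture as a means of inducing differentiation, and the comparison asks which transcripts differ between the cultures. The labels give no culture time or plate for the normal samples. A difference in time or vessel therefore cannot be told apart from restricted attachment. Each sample was hybridised to 1 single-colour Agilent array. The 8 arrays shared 1 slide and 1 scan, with the normal samples in slide row 1 and the adhesion-restricted samples in slide row 2, so row and culture condition cannot be told apart. The labels do not say whether the 4 samples of a condition were separate cultures, and the p-values therefore measure only the spread between these samples, which may be technical. Between 46.3% and 47.8% of non-control spots were well above background on each array and none was saturated, while the number of arrays limits the precision. Values are log2 signals relative to the 75th percentile of their own array, and levels are means ± SD.

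Culture condition separated the 8 samples clearly. The Pearson correlation across genes, which are not independent replicates, was 0.997 between normal samples, 0.994 to 0.995 between adhesion-restricted samples and 0.922 to 0.924 between conditions. Of 21685 genes tested with limma, 17155 (79.1%) differed at an adjusted p under 0.05, with 9131 higher and 8024 lower in adhesion-restricted culture. A change of at least 2-fold was found for 5544 genes, of which 3077 rose and 2467 fell. Among the 12993 protein-coding genes, 1567 rose and 1834 fell by that margin. The values of both conditions did not overlap for 16268 genes (75.02%), where chance gives 2.86%. The balance of higher and lower calls depended on the scaling: 8379 genes were higher and 8481 lower after quantile normalization, 4481 and 13243 after median scaling, 4680 and 12773 without scaling, and 11235 and 6434 with the authors' deposited series matrix values. Spike-in scaling, chosen after the data were seen, gave 5466 higher and 9592 lower, and 2236 and 3603 at 2-fold or more. At 2-fold or more, 1708 were higher and 4987 lower after median scaling, 1780 and 4742 without scaling, and 3846 and 1952 with the series matrix values. The median gene changed by 0.06 in the scaling used here, by -0.43 after median scaling, by -0.39 without scaling and by 0.23 with the series matrix values, and the changes below are relative to the array's 75th percentile. On every array the median signal, 3.97 to 4.13, lay under the lowest signal well above background, so median scaling rests on signal at background level. It lies close to no scaling, since the group medians differed by 0.0386 before scaling. Median scaling moves each change by -0.495, so smaller rises turn sign there. The series matrix moves each by 0.17, so smaller falls turn sign there.

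KRT77, a keratin of the suprabasal epidermis, was not well above background in any normal sample and was at least 76.9-fold higher in adhesion-restricted culture (adjusted p = 9.4e-09). THEM5, encoding an acyl-CoA thioesterase, was at least 204-fold higher (adjusted p = 2.6e-09), SBSN, encoding suprabasin, at least 106-fold higher (adjusted p = 1.9e-07), RDH12, encoding a retinol dehydrogenase, at least 46.6-fold higher (adjusted p = 1.8e-09), and DSG1, encoding the desmosomal cadherin desmoglein 1, at least 40.9-fold higher (adjusted p = 2.9e-07). These genes were likewise dim in every normal sample, so the figures are lower bounds set against the dimmest signal well above background. GPNMB, encoding a transmembrane glycoprotein, rose from 1.52 ± 0.02 to 8.89 ± 0.02 (SD, n = 4 each), a 165-fold change with an adjusted p of 2.8e-12. S100A8, encoding a calcium-binding subunit of calprotectin, rose 142-fold (adjusted p = 1.1e-11), and GPR15LG, encoding a ligand of the receptor GPR15, rose 133-fold (adjusted p = 2.2e-11). The largest decreases included SFTA1P, a pseudogene transcript, which was well above background in no adhesion-restricted sample and at least 28.6-fold lower (adjusted p = 3.7e-11). IL1B, encoding interleukin-1 beta, fell from 5.29 ± 0.02 to -1.004 ± 0.16 (SD, n = 4 each), or 78.2-fold (adjusted p = 1.7e-10), and FST, encoding the activin antagonist follistatin, fell 50.2-fold (adjusted p = 2.2e-11). CDH6, encoding a cadherin, was at least 28.2-fold lower, MYBL1, encoding a MYB-family transcription factor, at least 18.5-fold lower, FAM72A at least 15.4-fold lower, NTM, encoding neurotrimin, at least 13.7-fold lower and SKA1, encoding a kinetochore protein, at least 11.4-fold lower, each dim in all adhesion-restricted samples, with adjusted p of 4.9e-07, 6.8e-08, 1.5e-07, 6.6e-11 and 9.6e-11. The probe for FAM72A may also bind its near-identical paralogs, so that value is uncertain.

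Of the 42 gene lists fixed before the data were examined, 40 had at least 5 measured genes, and 21 of these differed from the other genes at an adjusted p under 0.05 in limma's camera test with a preset correlation. Among them 8 lists were higher and 13 lower. Only the G2/M and G1/S lists were also called with an estimated correlation, and fry, which does not compare a list with other genes, called 39. The suprabasal keratin, desmosome and fatty acid synthesis lists lost their calls although their estimated correlations (-0.0187, -0.02 and -0.0253) lay under the preset 0.01. A call lost in that setting thus need not mean that the members are correlated. Adjusted over the list alone, the numbers of rising and falling members were those found over all genes tested in all but 3 lists, which are named with their counts. Some list members that moved against the rest of a list are named here, and they were picked after their values were seen. Calls with no filter on dim probes compare a list with many probes at background level, which the scaling itself raises in adhesion-restricted arrays.

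Cornified envelope genes, which encode the cross-linked protein shell of terminally differentiated keratinocytes, rose as a list. Of the 29 measured, 25 rose, 3 fell and 1 did not pass the test. Their median change was 2.79, or 1.91 with the 10 genes that were dim throughout 1 condition set at their bounds and 1.35 after normexp background correction (adjusted p = 1.12e-05 by camera, adjusted p = 0.0958 with an estimated correlation). SPRR1B, encoding a small proline-rich envelope precursor, rose 41.5-fold from 1.91 ± 0.02 to 7.28 ± 0.06 (SD, n = 4 each), KRTDAP, encoding keratinocyte differentiation-associated protein, rose 74.3-fold and SPRR3 rose 27.5-fold. IVL, encoding involucrin, was dim in all normal samples and at least 3.77-fold higher in adhesion-restricted culture (adjusted p = 1.9e-05). TGM1, encoding the transglutaminase that cross-links envelope proteins, fell by 0.28 (adjusted p = 0.0028), a difference of -0.11 with an adjusted p of 0.0973 in the series matrix values. ANXA1 fell by 2.34 and CST6, dim in the adhesion-restricted samples, was at least 2.26-fold lower, while CSTA differed by -0.04 and did not pass. FLG, encoding filaggrin, was not well above background on any of the 8 arrays with any of its 3 probes and was not tested.

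**Figure D1:**
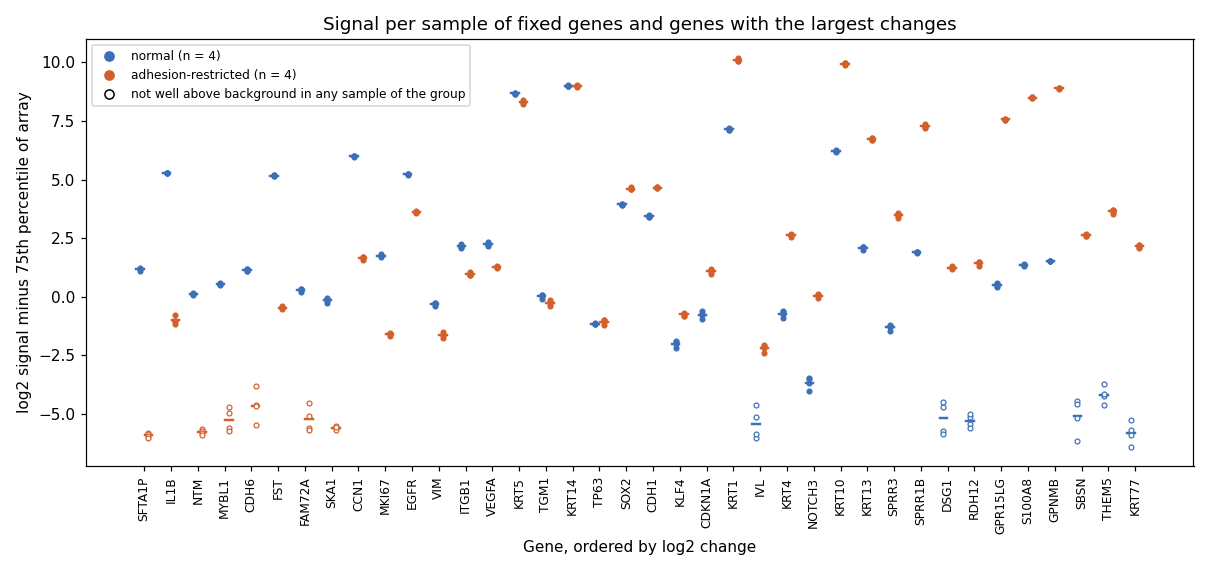
Normalised log2 signal of the tested fixed genes and the 16 genes with the largest changes in each of the 4 normal and 4 adhesion-restricted samples, relative to the 75th percentile of the array. Points are single samples, the short bars are group means, and open points mark genes well above background in no sample of that group. KRT10 lies at 6.22 in normal and 9.95 in adhesion-restricted culture on average, and MKI67 at 1.75 and -1.59.

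Suprabasal keratin genes showed the same direction, with 10 of 11 measured members higher and 1 lower, a median change of 3.44 (adjusted p = 0.000995 by camera, adjusted p = 0.0958 with an estimated correlation). KRT10 rose 13.2-fold from 6.22 ± 0.04 to 9.95 ± 0.02, and its partner KRT1 rose 7.78-fold from 7.14 ± 0.05 to 10.10 ± 0.06 (SD, n = 4 each). KRT13 and KRT4, the keratin pair of non-cornifying oral epithelium, rose 24.9-fold and 10.2-fold. KRT23, dim in normal culture, was at least 15.3-fold higher. KRT76 rose 80.9-fold and was well above background in 1 of the 4 normal samples, whereas KRT80 fell by 2.77. Among 20 genes of basal keratinocytes, 5 rose, 11 fell and 4 did not pass, and the list was not called (adjusted p = 0.223) except with no filter on dim probes (lower, adjusted p = 0.00182) and by fry (lower, adjusted p = 0.00149). Its balance depended on scaling, with a median of -0.18 here, -0.68 after median scaling, where 3 rose and 15 fell, and -0.01 in the series matrix values, where 9 rose and 9 fell. Within it KRT15 rose 9.52-fold and ITGA6, COL17A1, COL7A1 and DST rose by 0.76, 0.72, 0.50 and 0.35, while the hemidesmosome and laminin receptor genes ITGB4, ITGA3 and ITGB1 fell 3.66-fold, 2.36-fold and 2.31-fold and KRT5 fell by 0.37. KRT14 lay at 9.001 in normal and 8.999 in adhesion-restricted culture (adjusted p = 0.94), and its direction was open, with a difference of -0.46 without scaling (adjusted p = 1.55e-05), of 0.17 in the series matrix values (adjusted p = 0.000915) and of 0.23 as the mean of its 2 probes (adjusted p = 0.000359). TP63, encoding the transcription factor p63, differed by 0.08 (adjusted p = 0.18), by -0.38 without scaling (adjusted p = 0.000385), by 0.25 in the series matrix values (adjusted p = 0.00093) and by 0.12 without adhesion-restricted replicate 1 (adjusted p = 0.00945). For 7 keratin and S100 genes tied to hyperproliferative epidermis, 4 rose, 2 fell and 1 did not pass (adjusted p = 0.103 by camera). Camera called the list higher in every other scaling tried. Its adjusted p was 0.0276 after quantile normalization, 0.0231 after median scaling, 0.026 without scaling and 0.0188 after normexp. It was 0.0461 in the series matrix values and 0.0225 after spike-in scaling. The list was not called with an estimated correlation (adjusted p = 0.461 by camera). S100A9 rose 18.2-fold, KRT16 10.3-fold and KRT6B 3.11-fold, although KRT6B has near-identical paralogs. KRT17 fell by 0.36 and KRT6C by 0.11. The simple-epithelium keratin list had 4 measured genes, too few for the test, of which 3 fell and 1 rose. Of these, KRT18 fell 2.68-fold, and KRT8 fell 2.42-fold by its brightest probe while its probes disagreed in direction. KRT19, well above background in 3 of the 4 adhesion-restricted samples, differed by 0.57 (adjusted p = 0.026), a call lost after median scaling (0.07, adjusted p = 0.749) and when any 1 of 5 single samples was left out. KRT7 differed by -0.18 (adjusted p = 0.003) and by 0.08 after quantile normalization (adjusted p = 0.0974), so its direction was open.

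Proteases and protease inhibitors of the epidermis rose in 16 of 21 cases, fell in 4 and did not pass in 1, with a median of 1.63, or 1.37 with bounds and 0.54 after normexp (adjusted p = 0.00579 by camera, adjusted p = 0.238 with an estimated correlation). The kallikrein genes KLK11 and KLK8 rose 12.04-fold and 9.62-fold, KLK12, dim in normal culture, was at least 8.96-fold higher, and WFDC5 rose 8.79-fold. The inhibitor gene SLPI fell by 0.88 and the kallikrein genes KLK5, KLK6 and KLK9 fell by 0.61, 0.35 and 0.17. Barrier lipid genes rose in 11 of 16 cases, fell in 3 and did not pass in 2, and were not called (adjusted p = 0.148). Their members included ABCA12, the keratinocyte lipid transporter, which rose 25.1-fold, and SULT2B1, the cholesterol sulfotransferase, which was at least 9.77-fold higher. NIPAL4 rose 3.01-fold and LIPM, dim in normal culture, was at least 2.44-fold higher, while ABHD5, DEGS2 and SPTLC3 fell by 0.50, 0.41 and 0.36. Their median of 0.49 became -0.01 after median scaling, where 6 rose and 6 fell. Regulators of keratinocyte differentiation rose in 21 of 28 cases, fell in 5 and did not pass in 2, with a median of 0.85, or 0.35 after median scaling, where 16 rose and 8 fell (adjusted p = 0.000741 by camera, adjusted p = 0.121 with an estimated correlation). The grainyhead-like factor genes GRHL3 and GRHL1 rose 12.7-fold and 9.99-fold, KLF4 rose 2.41-fold, ELF3 was at least 5.63-fold higher, and NOTCH3 rose 13.1-fold and was well above background in 3 of the 4 normal samples. SOX9, JAG1, PRDM8, HEY1 and JAG2 fell by 2.93, 1.48, 0.96, 0.64 and 0.23.

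In the desmosome list, 8 of 10 genes rose and 2 fell, with a median of 1.61 (adjusted p = 0.0142 by camera, adjusted p = 0.101 with an estimated correlation). DSC2, DSC3 and PKP1 rose 7.26-fold, 5.09-fold and 4.38-fold, while PKP2 fell 5.54-fold and DSG2 fell by 0.82. Adherens, tight and gap junction genes rose in 17 of 23 cases, fell in 4 and did not pass in 2, with a median of 1.03, or 0.53 after median scaling, where 14 rose and 7 fell (adjusted p = 0.00174 by camera, adjusted p = 0.101 with an estimated correlation). The connexin genes GJB6, GJA1 and GJB2 rose 21.2-fold, 12.1-fold and 9.21-fold, NECTIN4 rose 14.2-fold, and CDH1, encoding E-cadherin, rose 2.33-fold from 3.43 ± 0.04 to 4.65 ± 0.03 (SD, n = 4 each). CLDN1, CDH3 and CTNNB1 fell by 0.90, 0.47 and 0.13. The list of mesenchymal transition genes was not called against other genes, with 7 of 15 rising, 7 falling and 1 not passing (adjusted p = 0.731 by camera), and was called lower by fry (adjusted p = 0.00455). After median scaling 3 rose and 10 fell. VIM, encoding vimentin, fell 2.49-fold, PDPN fell 5.44-fold, FN1, encoding fibronectin and dim in adhesion-restricted culture, was at least 1.19-fold lower, and TNC fell 3.46-fold, while LOX rose 4.88-fold.

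The measured genes of both cell-cycle lists fell in every scaling tried. All 43 measured G2/M genes fell, with a median change of -4.25, or -4.20 with bounds (adjusted p = 1.48e-18 by camera, adjusted p = 0.022 with an estimated correlation). CCNA2, encoding cyclin A2, fell 34.4-fold, BIRC5, encoding survivin, fell 30.8-fold from 6.22 ± 0.02 to 1.28 ± 0.03 (SD, n = 4 each), KIF2C fell 27.5-fold, and CENPA fell 30.9-fold and was well above background in 1 of the 4 adhesion-restricted samples. MKI67, the Ki-67 antigen gene, fell 10.2-fold from 1.75 ± 0.04 to -1.59 ± 0.05 (SD, n = 4 each). All 44 measured genes of the G1/S transition and DNA replication fell as well, with a median of -3.03, or -2.99 with bounds (adjusted p = 4.29e-18 by camera, adjusted p = 0.0486 with an estimated correlation). The replication helicase factor gene CDC45 fell 27.2-fold, ORC1 was at least 7.73-fold lower, and DSCC1 and MCM10, each well above background in 2 of the 4 adhesion-restricted samples, fell 29.5-fold and 25.7-fold. Replication-dependent histone genes fell in 10 of 15 cases, rose in 4 and did not pass in 1, with a median of -0.80, or -0.50 with bounds and -0.33 after normexp (adjusted p = 0.0411 by camera, adjusted p = 0.238 with an estimated correlation), and this call was lost, among other settings, after quantile normalization (adjusted p = 0.166), after median scaling (adjusted p = 0.0692) and without scaling (adjusted p = 0.0607). H2AC11, H3C4 and H3C10 fell 9.71-fold, 6.48-fold and 6.46-fold, whereas H2BC12 rose 2.65-fold and H2BC5, H2BC4 and H2BC8 rose by 0.63, 0.31 and 0.28, although near-identical histone genes can share a probe. The p53 target and cell-cycle inhibitor list was not called (adjusted p = 0.144), with 19 of 35 genes higher, 11 lower and 5 not passing, but was called higher after quantile normalization (adjusted p = 0.0133), after normexp (adjusted p = 0.0114) and by fry (adjusted p = 1.156e-07). The balance turned with scaling: 12 rose and 20 fell after median scaling, 12 and 18 without scaling, and the median of 0.21 became -0.29 and -0.25 there. Its members CDKN1C, GADD45G, TP53INP1 and BTG1 rose 11.7-fold, 9.24-fold, 7.17-fold and 5.24-fold, and CDKN1A, encoding p21, rose 3.62-fold.

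**Figure D2:**
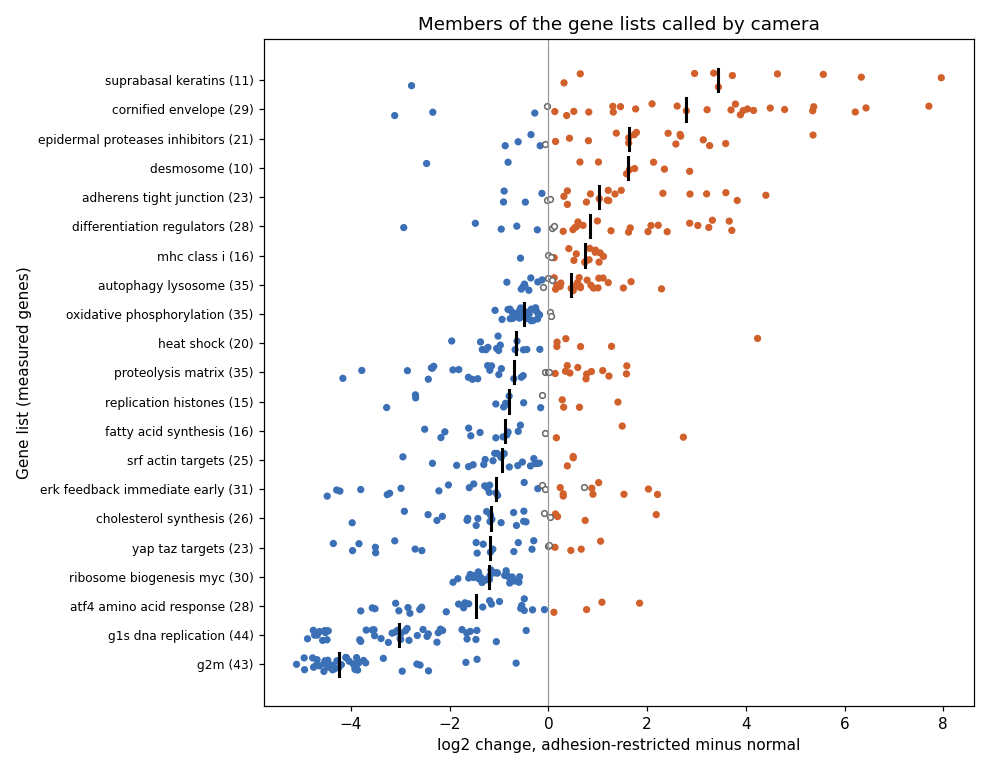
Log2 change from normal to adhesion-restricted culture for every measured member of the 21 gene lists called by camera, with 1 point per gene and a bar at the list median, genes dim in 1 condition at their measured values. Filled points passed the adjusted p threshold. All 43 G2/M genes and all 44 G1/S genes lie below 0, and the cornified envelope list has its median at 2.79.

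Ribosome biogenesis genes fell in all 30 measured cases, with a median of -1.22 (adjusted p = 1.99e-11 by camera, adjusted p = 0.0958 with an estimated correlation), and FBL, encoding the rRNA methyltransferase fibrillarin, and BOP1 fell 3.82-fold and 3.57-fold, followed by MYBBP1A and RRP12 with 3.07-fold and 3.003-fold. The ribosomal protein list had 13 of 41 higher, 17 lower and 11 not passing, none by 2-fold, and no call (adjusted p = 0.44), although the list was called lower without scaling (adjusted p = 0.000749), where all 41 fell, after median scaling (adjusted p = 0.000434) and after quantile normalization (adjusted p = 0.00662). Its median of -0.03 turned to 0.14 in the series matrix values, where 26 rose and 7 fell. RPL35, RPS3 and RPL14 fell by 0.47, 0.41 and 0.41. RPL3 differed by 0.32 (adjusted p = 4.6e-06), by -0.18 after median scaling (adjusted p = 0.00442) and by -0.14 without scaling (adjusted p = 0.0252), so its direction was open. Oxidative phosphorylation genes fell in 33 of 35 cases and did not pass in 2, with a median of -0.49, or -0.26 after normexp, where 26 fell and 3 rose (adjusted p = 3.9e-08 by camera, adjusted p = 0.101 with an estimated correlation). CYC1, encoding cytochrome c1, fell 2.12-fold, CYCS, encoding cytochrome c, fell 1.92-fold by its brightest probe while its probes disagreed in direction, SDHD fell 1.77-fold and COX8A fell 1.72-fold. Cholesterol synthesis and uptake genes fell in 20 of 26 cases, rose in 4 and did not pass in 2, with a median of -1.16 (adjusted p = 4.73e-05 by camera, adjusted p = 0.113 with an estimated correlation). ACAT2 fell 7.57-fold, INSIG1 5.42-fold and DHCR7 4.79-fold, while SC5D, TM7SF2, PMVK and LSS rose by 2.18, 0.74, 0.18 and 0.14. After median scaling and without scaling, 2 members of this list rose and 24 fell. Fatty acid synthesis genes fell in 12 of 16 cases, rose in 3 and did not pass in 1, with a median of -0.88 (adjusted p = 0.00185 by camera, adjusted p = 0.0958 with an estimated correlation). FADS1, FASN and ELOVL6 fell 5.69-fold, 4.53-fold and 4.29-fold, whereas DGAT2, which makes triglycerides, rose 6.65-fold, ACSL1 rose by 1.49 and LPIN2 by 0.16. In this list 2 rose and 14 fell after median scaling and without scaling. Genes of the ATF4 amino acid response fell in 24 of 28 cases and rose in 4, with a median of -1.48 (adjusted p = 2.77e-06 by camera, adjusted p = 0.0958 with an estimated correlation). CTH, CHAC1, ASNS, the asparagine synthetase gene, and TRIB3 fell 13.965-fold, 11.9-fold, 11.4-fold and 8.56-fold. VLDLR, NUPR1, DDIT3 and AARS1 rose by 1.84, 1.08, 0.77 and 0.11. Here 3 rose and 25 fell after median scaling and without scaling.

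YAP/TAZ target genes fell in 17 of 23 cases, rose in 4 and did not pass in 2, with a median of -1.18 (adjusted p = 0.000371 by camera, adjusted p = 0.0958 with an estimated correlation). CCN1, a matricellular protein gene, fell 20.5-fold from 6.01 ± 0.02 to 1.65 ± 0.06 (SD, n = 4 each), FJX1 fell 15.7-fold, F3, the tissue factor gene, 14.3-fold and NT5E 11.4-fold, while GLS2, DLC1, AMOTL1 and NUAK2 rose by 1.05, 0.66, 0.45 and 0.13. After median scaling and without scaling, 2 of the YAP/TAZ targets rose and 20 fell. CCN2 was well above background on only 3 of the 8 arrays and was not tested. SRF and actin cytoskeleton genes fell in 22 of 25 cases and rose in 3, with a median of -0.94 (adjusted p = 4.73e-05 by camera, adjusted p = 0.238 with an estimated correlation). FLNA, encoding filamin A, fell 7.73-fold, ACTN1 5.10-fold, PDLIM7 3.63-fold and TAGLN 3.07-fold, whereas ACTN4 and FHL1 rose by 0.50 each. These rises depended on scaling. After median scaling, without scaling and after spike-in scaling, 0 members of the list rose and 22 fell. ERK feedback and immediate early genes fell in 19 of 31 cases, rose in 9 and did not pass in 3, with a median of -1.06 (adjusted p = 0.026 by camera, adjusted p = 0.306 with an estimated correlation), a call lost, among other settings, after quantile normalization (adjusted p = 0.0732), after median scaling (adjusted p = 0.16) and without scaling (adjusted p = 0.12). DUSP6, an ERK phosphatase gene, fell 22.4-fold, FOSL1 fell 13.97-fold, and ETV5 and ETV4 were at least 5.83-fold and 4.53-fold lower. Protease, inhibitor and matrix genes of tissue remodelling fell in 20 of 35 cases, rose in 12 and did not pass in 3, and 21 fell adjusted over the list alone. Their median was -0.70 (adjusted p = 0.0278 by camera, adjusted p = 0.232 with an estimated correlation), and the call was lost, among other settings, after quantile normalization (adjusted p = 0.078), after median scaling (adjusted p = 0.109) and without scaling (adjusted p = 0.099). THBS1, encoding thrombospondin 1, fell 17.9-fold, MMP10 13.8-fold and SERPINE2 5.41-fold, and PLAT, well above background in 3 of the 4 adhesion-restricted samples, fell 7.25-fold.

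The growth factor ligand and receptor list was not called by camera (adjusted p = 0.379) except with no filter on dim probes (lower, adjusted p = 0.0126), with 9 of 21 genes higher, 10 lower and 2 not passing, and its median of 0.01 differed in sign from its mean of -0.36. After median scaling and without scaling 4 were higher and 14 lower, and in the series matrix values 11 were higher and 9 lower. AREG, encoding amphiregulin, fell 12.8-fold, MET and NRG1 fell 7.93-fold and 7.96-fold, and EGFR fell 3.07-fold from 5.23 ± 0.02 to 3.61 ± 0.04 (SD, n = 4 each), while FGFR3 rose 4.60-fold. TGF-beta and BMP targets went both ways, with 11 of 22 higher, 9 lower and 2 not passing (adjusted p = 0.943), and 10 lower adjusted over the list alone. After median scaling and without scaling 8 were higher and 12 lower. ID2 and BAMBI rose 15.4-fold and 8.30-fold, TGFB2, dim in adhesion-restricted culture, was at least 8.9997-fold lower and PMEPA1 fell 6.65-fold. WNT pathway genes also split, 8 of 16 each way (adjusted p = 0.894), with a median of 0.09, a mean of -0.01 and a test in the direction of the mean, while 6 rose and 8 fell after median scaling. The WNT antagonist gene DKK1 fell 24.2-fold, WNT7A fell 7.02-fold, WNT5A rose 8.80-fold, and WNT4, dim in normal culture, was at least 3.25-fold higher. Of 18 stemness markers, 9 rose, 7 fell and 2 did not pass (adjusted p = 0.651), while 6 rose and 9 fell after median scaling and without scaling. SOX2 rose 1.59-fold from 3.94 ± 0.02 to 4.61 ± 0.04 (SD, n = 4 each) and KLF5 rose 3.92-fold. NANOG, dim in normal culture, was at least 3.85-fold higher and POU5F1 rose 5.29-fold, although both have near-identical pseudogenes that can share a probe, and ABCG2, dim in adhesion-restricted culture, was at least 1.19-fold lower.

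Antigen presentation genes of MHC class I rose in 13 of 16 cases, fell in 1 and did not pass in 2, with a median of 0.74 (adjusted p = 0.00192 by camera, adjusted p = 0.121 with an estimated correlation). After median scaling 8 rose and 4 fell with a median of 0.25, and without scaling 8 rose and 4 fell with a median of 0.285. ERAP1, the peptide-trimming aminopeptidase gene, HLA-F, HLA-G and HLA-C rose 2.16-fold, 2.07-fold, 2.04-fold and 1.94-fold, and TAP2 fell by 0.57. HLA genes are similar enough in sequence to share probes. Interferon response genes were not called (adjusted p = 0.264), with 13 of 40 higher, 18 lower and 9 not passing, and were called lower with no filter on dim probes (adjusted p = 0.000374) and by fry (adjusted p = 6.796e-07). Their balance depended on scaling, with 8 higher and 27 lower after median scaling and without scaling, and 19 higher and 16 lower in the series matrix values. OASL and CXCL10 fell 9.15-fold and 8.89-fold, CXCL11 was at least 3.60-fold lower, and GBP2 was at least 38.4-fold higher. In the NF-kappaB and inflammation list, 15 of 33 genes rose, 16 fell and 2 did not pass (adjusted p = 0.731), and 16 rose adjusted over the list alone. After median scaling 11 rose and 20 fell, and in the series matrix values 16 rose and 14 fell. IL1A fell 31.7-fold, whereas IL1RN, encoding the interleukin-1 receptor antagonist, rose 15.1-fold, and the chemokine gene CCL5, dim in adhesion-restricted culture, was at least 1.91-fold lower. Autophagy and lysosome genes rose in 23 of 35 cases, fell in 9 and did not pass in 3, with a median of 0.46 that became -0.04 after median scaling, where 13 rose and 17 fell, and 0.00 without scaling, where 15 rose and 17 fell (adjusted p = 0.0217 by camera, adjusted p = 0.23 with an estimated correlation). The call was lost after median scaling (adjusted p = 0.109), without scaling (adjusted p = 0.0805), after spike-in scaling (adjusted p = 0.0909) and with no filter on dim probes (adjusted p = 0.223). CTSH, encoding cathepsin H and dim in normal culture, was at least 3.58-fold higher, and GABARAPL1, ULK1 and LAMP1 rose 3.19-fold, 2.86-fold and 2.32-fold. Heat shock genes fell in 14 of 20 cases and rose in 6, with a median of -0.66, or -0.57 with bounds (adjusted p = 0.0253 by camera, adjusted p = 0.232 with an estimated correlation). They were not called, among other settings, after quantile normalization (adjusted p = 0.0553), after median scaling (adjusted p = 0.0885) or without scaling (adjusted p = 0.0795). HSPD1, HSPA8 and HSPE1 fell 3.89-fold, 2.60-fold and 2.53-fold, while CRYAB, encoding alpha-B crystallin, rose 18.8-fold.

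Of the other stress lists none was called by camera in the scaling used here. Hypoxia and glycolysis genes rose in 12 of 35 cases, fell in 22 and did not pass in 1 (adjusted p = 0.0585), with a call toward lower in the series matrix values (adjusted p = 0.0188) and with no filter on dim probes (adjusted p = 0.000349). VEGFA was 1.97-fold lower, LOXL2 7.89-fold lower, STC2 7.002-fold lower and SLC2A1, the GLUT1 glucose transporter gene, 3.83-fold higher, and EGLN3, dim in normal culture, was at least 4.01-fold higher. Unfolded protein response genes rose in 14 of 21 cases, fell in 6 and did not pass in 1 (adjusted p = 0.148), with HSPA5, the BiP chaperone gene, 2.60-fold, DNAJB9 1.85-fold and PDIA3 1.55-fold higher, but the list was called higher after quantile normalization (adjusted p = 0.00878) and its median of 0.30 became -0.16 without scaling, where 3 rose and 12 fell, and -0.20 after median scaling, where 3 rose and 13 fell. HSP90B1 rose 1.48-fold, a call lost without scaling (0.11, adjusted p = 0.0551). NRF2 targets rose in 9 of 27 cases, fell in 15 and did not pass in 3 (adjusted p = 0.311). A call toward lower was found with no filter on dim probes (adjusted p = 0.00194), and one toward higher by fry (adjusted p = 0.00322). HMOX1, encoding heme oxygenase 1, rose 5.97-fold, AKR1B10 4.75-fold, AKR1C1 3.96-fold and AKR1C3 3.38-fold, although the AKR1C genes are near-identical. Apoptosis and anoikis genes rose in 15 of 28 cases, fell in 11 and did not pass in 2 (adjusted p = 0.44), but 10 rose and 17 fell both after median scaling and without scaling. BMF, a proapoptotic BH3-only gene, and TNFSF10, encoding TRAIL, rose 7.11-fold and 4.41-fold and HRK rose 3.07-fold, while BCL2 fell 5.33-fold and was well above background in 1 of the 4 adhesion-restricted samples.

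Markers of other cell types were not called by camera in either direction. Mucin and secretory genes rose in 3 of 9 cases, fell in 4 and did not pass in 2 (adjusted p = 0.74), with a median of 0.09 and a mean of -0.10, and 2 rose and 6 fell after median scaling. MUC1 rose 4.01-fold, PSCA, dim in normal culture, was at least 1.80-fold higher and TFF2, well above background in 2 of the 4 samples of each condition, rose by 0.40. MUC4 fell by 0.25, while AGR2 and SPDEF fell 3.09-fold and 2.67-fold and CEACAM1, well above background in 3 of the 4 adhesion-restricted samples, fell 2.30-fold. Fibroblast markers rose in 5 of 6 cases and fell in 1 (adjusted p = 0.148), or rose in 3 and fell in 2 after median scaling, with C1S 2.42-fold, COL1A1 2.16-fold and C1R 1.91-fold higher, PDGFRB higher by 0.43 and FBLN1 by 0.31, and MFAP5 9.12-fold lower. Of 8 immune cell markers, 2 rose, 2 fell and 4 did not pass (adjusted p = 0.9), with a median of 0.03 and a test in the direction of lower, while 1 rose and 4 fell after median scaling and 3 rose and 1 fell in the series matrix values. ITGAM, well above background in 2 of the 4 normal samples, rose 4.47-fold. FCER1G differed by -0.43. CD14 differed by -0.30 and by -0.13 in the series matrix values (adjusted p = 0.191). PTPRC differed by 0.39 (adjusted p = 0.025) and by -0.10 after median scaling (adjusted p = 0.461), so its direction was open. The endothelial list had 3 measured genes, too few for the test, of which 2 fell and 1 did not pass, with EGFL7 1.52-fold lower and CDH5 1.22-fold lower, the second a call lost in the series matrix values (-0.12, adjusted p = 0.2).

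**Figure D3:**
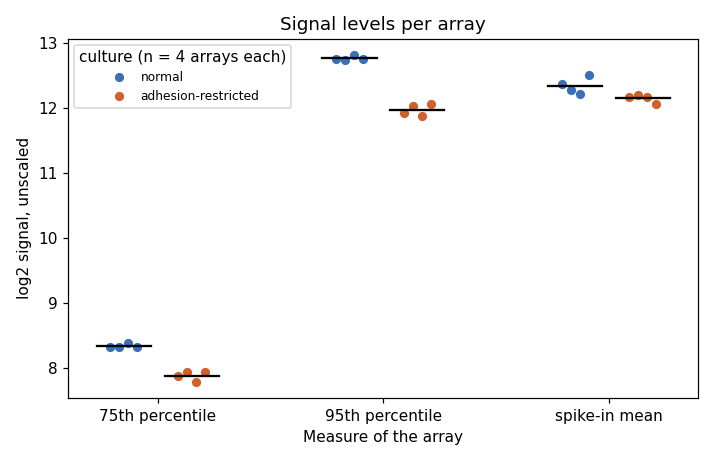
Unscaled log2 signal at the 75th and 95th percentiles of each array and the mean of its 7 spike-in controls that were well above background throughout, as single arrays with group means as bars. The 75th percentile averages 8.33 in normal and 7.88 in adhesion-restricted arrays, the 95th percentile 12.76 and 11.97, and the spike-in mean 12.34 and 12.15.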

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

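In groups of 4 samples, a sample counts as far from the others when its gap to the nearest takes most of the group's range, which chance gives in about 1 of 20 groups. Among 486 such groups, of 8 array measures, 40 gene lists and 195 genes, 32 held such a sample, against 24.3 that chance gives. They lay in normal and adhesion-restricted groups equally, 16 each, and the samples with the most, normal replicate 1, normal replicate 3 and adhesion-restricted replicate 1, had 6 each. No explanation was tested for these samples.

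The array of normal replicate 3 had the highest 75th percentile in its group, 8.385, against 8.314 to 8.321 in the others, and the highest 95th percentile, 12.81 against 12.74 to 12.75. In mean signal of a list, adhesion-restricted replicate 1 was low for epidermal proteases and inhibitors (1.303) and for NRF2 targets (3.292), and normal replicate 1 was low for NF-kappaB and inflammation genes (0.6372) and for autophagy and lysosome genes (2.894).

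Among normal samples, the sample apart was replicate 1 for GJA1 (3.096), MMP10 (3.077), CYCS (5.128) and EGLN3 (-5.963), replicate 2 for FOSL1 (1.394) and WNT4 (-5.486), replicate 3 for KRT13 (2.011), INSIG1 (1.743), COX8A (8.244) and RPL35 (8.999), and replicate 4 for PKP2 (2.423) and DKK1 (3.972). Among adhesion-restricted samples it was replicate 1 for CCN1 (1.562), TNC (-0.3231), HLA-F (4.82) and HLA-C (4.244), replicate 2 for KRT23 (-0.0792), NIPAL4 (1.878), THBS1 (0.8523) and H3C10 (0.5614), replicate 3 for KRT15 (10.43), SULT2B1 (-0.5724) and F3 (1.606), and replicate 4 for KRT10 (9.911), ITGB1 (1.034) and ID2 (5.205). EGLN3 and WNT4 were dim in all normal samples. The 75th percentile, highest in normal replicate 3 among normal arrays, is subtracted from every gene. That sample's low values for KRT13, INSIG1, COX8A and RPL35 may therefore not be separate from its array's flag, which was not tested.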

How the results depend on the processing

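Spike-in scaling and the set test among protein-coding genes only were chosen after the data were seen, and the cause was not tested for any change given here. The number of genes past the threshold split as 9131 higher and 8024 lower; after median scaling the split was 4481 and 13243, without scaling 4680 and 12773, and after spike-in scaling 5466 and 9592, or 2236 and 3603 at 2-fold or more. With no filter on dim probes, more genes were tested, and 32610 differed, 24338 of them higher. Before scaling, the array medians, which lie at background level, differed by 0.0386 (SE 0.039), while the 75th percentile fell by 0.457 (SE 0.038). Subtracting that percentile by itself raises probes at background level, so these higher calls are no count of raised transcripts. Lists called lower in this setting were compared with such probes too. At 2-fold or more, 1708 genes were higher and 4987 lower after median scaling, 1780 and 4742 without scaling, and 1530 and 1437 after normexp, which calls 2967 genes; 4737 were higher with no filter on dim probes. Of the 5544 genes changed at least 2-fold, the shared calls, all with the same sign, numbered 4701 after quantile normalization, 4175 after median scaling, 4247 without scaling, 2834 after normexp, 5028 with the series matrix values, 4702 after spike-in scaling and 4088 among probes well above background on all 8 arrays. Normexp used median signals, and leaving out saturated probes moved nothing, since 0 probes were saturated. Leaving out each sample in turn gave 16634 to 17028 genes, 5535 to 5566 of them at 2-fold or more, and no list changed its call. The replicate number was also the slide column in both groups, so the replicate block is a column block too. Same-numbered samples' deviations correlated at 0.11, 0.029, -0.0028 and 0.078, and 2 of the 4 matched best with their own number. These small values gave no clear pairing but do not exclude one. With the replicate block, 16988 genes differed, 9036 higher and 7952 lower, 5542 by 2-fold or more, and no list changed its call. Signal over background limits the dim genes: 514 genes were dim in all normal samples and 506 in all adhesion-restricted samples, so that their changes are bounds.

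The adjusted p of each list whose call changed is given in parentheses. The list of NRF2 targets turned from lower to higher by fry (0.00322), which asks only whether its members move one way. With an estimated correlation, lists that lost the call were cornified envelope (0.0958), suprabasal keratins (0.0958), epidermal proteases inhibitors (0.238), differentiation regulators (0.121), desmosome (0.101), adherens tight junction (0.101), cholesterol synthesis (0.113), fatty acid synthesis (0.0958), ATF4 amino acid response (0.0958), MHC class I (0.121), YAP/TAZ targets (0.0958), SRF and actin targets (0.238), ERK feedback immediate early (0.306), proteolysis matrix (0.232), heat shock (0.232), oxidative phosphorylation (0.101), ribosome biogenesis (0.0958), autophagy lysosome (0.23) and replication histones (0.238). With no filter on dim probes, the list that lost the call was autophagy lysosome (0.223). With no filter on dim probes, lists that gained the call were basal keratinocyte (0.00182), hypoxia glycolysis (0.000349), interferon response (0.000374), EGFR ligands receptors (0.0126), NRF2 targets (0.00194) and ribosomal proteins (0.00364). By fry, lists that gained the call were basal keratinocyte (0.00149), hyperproliferation keratins (5.334e-11), barrier lipid (2.663e-09), EMT mesenchymal (0.00455), hypoxia glycolysis (3.343e-06), unfolded protein response (5.283e-08), interferon response (6.796e-07), NF-kappaB inflammatory (1.64e-05), EGFR ligands receptors (1.49e-07), TGF-beta targets (0.000128), WNT targets (1.418e-06), stemness markers (3.378e-07), p53 target and CDK inhibitors (1.156e-07), apoptosis anoikis (6.542e-07), ribosomal proteins (0.00945), mucins secretory (5.537e-06) and fibroblast markers (1.186e-09). After quantile normalization, lists that lost the call were ERK feedback immediate early (0.0732), proteolysis matrix (0.078), heat shock (0.0553) and replication histones (0.166). After quantile normalization, lists that gained the call were hyperproliferation keratins (0.0276), unfolded protein response (0.00878), p53 target and CDK inhibitors (0.0133) and ribosomal proteins (0.00662). After median scaling, lists that lost the call were ERK feedback immediate early (0.16), proteolysis matrix (0.109), heat shock (0.0885), autophagy lysosome (0.109) and replication histones (0.0692). After median scaling, lists that gained the call were hyperproliferation keratins (0.0231) and ribosomal proteins (0.000434). Without scaling, lists that lost the call were ERK feedback immediate early (0.12), proteolysis matrix (0.099), heat shock (0.0795), autophagy lysosome (0.0805) and replication histones (0.0607). Without scaling, lists that gained the call were hyperproliferation keratins (0.026) and ribosomal proteins (0.000749). After normexp, lists that lost the call were proteolysis matrix (0.0502) and replication histones (0.126). After normexp, lists that gained the call were hyperproliferation keratins (0.0188), unfolded protein response (0.0114), p53 target and CDK inhibitors (0.0114) and ribosomal proteins (0.00643). With the series matrix values, lists that gained the call were hyperproliferation keratins (0.0461) and hypoxia glycolysis (0.0188). After spike-in scaling, the list that lost the call was autophagy lysosome (0.0909). After spike-in scaling, the list that gained the call was hyperproliferation keratins (0.0225). Among probes well above background on all 8 arrays, lists that lost the call were ERK feedback immediate early (0.15), proteolysis matrix (0.0759), heat shock (0.052) and replication histones (0.0784). Among protein-coding genes only, lists that lost the call were ERK feedback immediate early (0.139), proteolysis matrix (0.147), heat shock (0.112) and replication histones (0.142). With the mean of all retained probes, the list that lost the call was replication histones (0.0504).

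Single genes were followed through the settings only for 195 named genes. Among these, KRT14 turned direction, to 0.17 with the series matrix values and 0.23 with the mean of its probes. TP63 turned to -0.42 after median scaling and -0.38 without scaling. KRT7 turned to 0.084 after quantile normalization and 0.10 after normexp. RPL3 turned to -0.18 after median scaling and -0.14 without scaling. PTPRC turned to -0.10, -0.063 and -0.0023 after median scaling, without scaling and after normexp. Calls of other genes also moved: TGM1, CDH5 and CD14 were not called with the series matrix values, HSP90B1 not after median scaling or without scaling, and KRT19 not after quantile normalization, median scaling, normexp or spike-in scaling, nor without scaling. PTPRC lost its call in further settings, among them the replicate block (adjusted p = 0.0802). Among 195 named genes, 154 could be tested among probes well above background on all 8 arrays, and all 154 kept direction and call. Members picked because they moved against their list were not followed in this way. Median scaling moves each change by -0.495 and leaving out scaling moves it by -0.457. Small rises, such as those of LSS, PMVK, DST and FBLN1, therefore turn sign in both settings. The series matrix values move each change by 0.17, so the small falls of KRT6C and CTNNB1 turn sign there.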

Other observations

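The gene families given here were chosen after the data were seen, from 344 families of at least 6 protein-coding genes that share a symbol stem. Of these, 19 were called by camera with the preset correlation, 6 higher and 13 lower, and 0 with an estimated correlation. All 9 measured ABCA genes, which encode lipid transporters, rose, with a median of 2.30 (adjusted p = 0.00301, adjusted p = 0.621 with an estimated correlation), ABCA12 by 25.1-fold and ABCA1 by 6.34-fold, and ABCA3, dim in normal samples, was at least 6.89-fold higher. All 8 metallothionein (MT) genes fell, with a median of -3.01 (adjusted p = 0.00301, adjusted p = 0.621 with an estimated correlation), led by MT1E and MT2A with 21.5-fold and 21.4-fold, although metallothionein genes are near-identical and can share probes. All 9 protocadherin beta (PCDHB) genes rose, with a median of 1.75, or 1.62 with bounds (adjusted p = 0.0267, adjusted p = 0.621 with an estimated correlation), and 14 of 16 GOLGA genes rose (median 1.11, adjusted p = 0.0126, adjusted p = 0.621 with an estimated correlation), both families with near-identical members.

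Genes of the mitochondrial ribosome fell, 44 of 49 in the MRPL family with a median of -0.77 (adjusted p = 2.24e-06, adjusted p = 0.621 with an estimated correlation) and 26 of 28 in the MRPS family with a median of -0.68 (adjusted p = 0.000534, adjusted p = 0.637 with an estimated correlation). Nucleoporin (NUP) genes fell in 20 of 21 cases with a median of -0.996 (adjusted p = 0.00125, adjusted p = 0.621 with an estimated correlation), and RNA polymerase subunit (POLR) genes fell in 26 of 30 cases with a median of -0.80 (adjusted p = 0.0017, adjusted p = 0.636 with an estimated correlation). These medians kept their sign after quantile normalization, after median scaling, without scaling and after spike-in scaling.

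Of the tests below, those on dim genes, on the spike-in controls and the 95th percentile, and on zinc finger genes were chosen after the result had been seen. All 35 splits of the 8 samples into 4 and 4 were counted once. For the number of genes past the threshold, 1 of the 35 splits, the real one, reached 17155, and the highest of the others was 0. For genes changed at least 2-fold, 1 of 35 reached 5544 and the highest other was 0. For gene lists, 1 of 35 reached 21 and the highest other was 17. The share of 1 in 35 is under the 0.05 level and is the smallest possible. Each mixed split puts the difference between the conditions inside its groups, so the splits show only that the calls follow the division by condition. They cannot exclude slide row. Nor can they exclude a chance difference between cultures, if the samples of a condition came from a single culture. Splits with 3 samples of 1 condition and 1 of the other in a group called 14 to 17 lists, and splits with 2 of each called 0 or 1.

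Dim genes were higher in adhesion-restricted culture after scaling: of 10 equal groups of genes ordered by mean signal, the dimmest had a median difference of 0.33 and the brightest one of -0.17. Before scaling, the genes of the 3 dimmest groups had a median difference of -0.162 (SE 0.04), and relative to the spike-in controls one of 0.030 (SE 0.089), so that a rise of the dim transcripts themselves stays open, since a yield difference between the arrays was not excluded. After scaling, their median difference was 0.294, where the scaling constants of the groups differed by 0.457. Whether the scaling constant alone raised these genes stays open too, because the same interval relative to the spike-in controls allows both no rise and a rise.

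The 75th percentile of signal was lower in adhesion-restricted arrays, by 0.457 (SE 0.038). The spike-in controls fell by 0.192 (SE 0.069), less than the percentile by 0.265 (SE 0.09), which argues against an equal yield loss as the whole cause and leaves it open as part of it. The 95th percentile fell by 0.792 (SE 0.044), more than the 75th, which argues against a single equal loss of all transcripts. The share of signal in the 100 brightest probes was 3.71 percentage points higher (SE 0.12). This was under the 5 points set beforehand for a few abundant transcripts as the cause. That bar was not tied to the size of the 75th percentile's fall. It therefore cannot show how much of the fall such transcripts explain. A change in the makeup of the transcripts with culture condition stays open, as does slide row, which cannot be told apart from culture.

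Zinc finger (ZNF) genes were higher relative to the other genes: 242 of 394 rose and 83 fell (adjusted p = 0.000285, adjusted p = 0.621 with an estimated correlation). Their median was 0.356, above the upper limit of the central range (0.0977) and the highest value (0.265) of 10000 random lists matched on mean signal, which argues against dimness alone. The random lists were drawn gene by gene and carry no correlation among ZNF genes. Their range may therefore be too narrow, and the strength of this argument is uncertain. The direction depended on scaling, with medians of 0.25 after quantile normalization, 0.09 after spike-in scaling, -0.14 after median scaling and -0.10 without scaling, so the rise may be one relative to the other genes only. An effect of culture condition on these genes stays open as an untested hypothesis.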
